A study of Salmo trutta with 8 samples.

How the data were processed

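RNA from gill, gut, kidney and liver of wild adult brown trout (Salmo trutta) was profiled by sequencing of messenger RNA. The fish came from the river Hayle, where the labels give chronic exposure to metals, and from the river Teign, the control. Each of the 8 libraries was made from pooled fish, 5 per pool for Hayle and 10 for Teign according to the series design, so each river and tissue has 1 library. The tissue labels describe gut as stomach and intestine and kidney as trunk kidney. The number of fish per pool goes with the river, and the labels used here give no sex, reproductive stage, sampling date or sequencing batch.

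The submitters' design text says that reads from embryos and from multiplexed tissue libraries of both populations were assembled into a transcriptome. Abundance was estimated with RSEM, per the submitters' processing notes, and its version was not given in the sources used here. The aligner used under RSEM was likewise not given in the sources used here. The deposited expected counts, named so per the file headers, are estimated read numbers per gene ID and need not be whole; 55.7% of the values were 0, and 78.7% of those above 0 were whole within 0.001. The deposited TPM values are, per the file headers, length-corrected abundances scaled to a common total in each library. The deposited FPKM values are, per the file headers, fragment numbers scaled by length and by library total, and were not used in a test. Each gene ID carries the contigs assigned to it, 202994 contigs over 96683 IDs. The files do not pair IDs with gene names, and 0 of the 96683 IDs matched the reference table of gene names, so genes are given by ID, and the gene and cell type lists fixed before the data were examined were not used here. Reads shared by near-identical contigs are divided by estimation, so the values of single IDs from duplicated genes are uncertain.

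Expected counts were rounded to whole numbers. Library totals ran from 1487186 to 2178331 reads. Gene IDs were filtered with filterByExpr in edgeR 4.0.16 with tissue as group (minimum count 10, minimum total 15), which kept 20345 IDs, and libraries were scaled by TMM. In the comparison of rivers within a tissue, the log2 ratio of Hayle to Teign was taken from TMM-scaled CPM with a prior count of 2, for IDs with at least 20 reads over both libraries. An ID was counted as higher or lower where the ratio was at least 2 on the log2 scale in size and the exact (Clopper-Pearson) 95% counting interval lay beyond a 2-fold difference. With 1 library per group there is no replicate check, and no p-value is given for that comparison. Counting intervals, and floors of 3 counts where a count is 0, cover counting error only, since reads without molecular identifiers are not independent molecules. A ratio to a floor takes the count of the other river as exact.

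A river difference shared by the tissues was tested with edgeR's robust quasi-likelihood test on all 8 libraries, with tissue as block and river as term, at a Benjamini-Hochberg adjusted p of 0.05. Its residual, with 3 degrees of freedom, is how the river difference varies between tissues. An ID without reads in any library of a river, or with reads in a single tissue pair, is fitted exactly. No such spread is measured for it, and its p-value rests on the spread of other IDs. The tissues of a river may come from the same fish, so the p-values speak of these 2 pools and not of the rivers or of metal exposure. The SE printed beside a shared log2 fold change is that fold change divided by the square root of the test's F statistic. It was not estimated by itself and can understate the error where a river has few reads. Tissue differences were tested with the same tool, each tissue against the mean of the other 3 with river as covariate, at an adjusted p of 0.05 and a log2 fold change of at least 2 in size. A tissue-restricted ID had at least 80% of its CPM in that tissue in both rivers and at least 3 reads in each of that tissue's libraries. The numbers of calls among restricted IDs were set beside those of the other IDs at matched abundance.

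The rule for printed IDs, fixed before the data were examined, takes the largest fold changes past the shared test with the same sign in all 4 tissues, at most 2 higher and 2 lower where no gene names are given. The designs and most alternatives were also fixed then. The alternatives were DESeq2 1.42.0 size factors and its Wald test, limma 3.58.1 (limma-trend), scaling by library totals, looser and stricter filters, other thresholds, a prior count of 0.5, TPM ratios with a pseudocount of 1, fits without the block or covariate, and fits without each library or tissue pair. A filter on the reads of each tissue pair, and fits without the 10 most abundant IDs of each library, were chosen after seeing the data.

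The scripts were tested on simulated counts with 200 changed IDs, drawn from IDs with at least 200 reads over the 8 libraries. Recovery of sparser IDs was not simulated. The 57 lower calls of the shared test that were nearly absent from Hayle had a median of 102 Teign reads. For the shared test, run on 19224 IDs, 92 of 100 IDs changed 4-fold and 99 of 100 changed 16-fold were recovered, with 3 false calls. Simulated counts without a change, run on 19111 IDs, gave 0 calls. For the gill tissue test, run on 17369 IDs, 50 of 100 IDs changed 4-fold, which is the size threshold itself, and 100 of 100 changed 16-fold were recovered, with 2 false calls. For the size rule within gill with counting error only, run on 15483 IDs, 37 of 87 IDs changed 4-fold and 93 of 93 changed 16-fold were recovered, with 1 false call. With the dispersion fitted to the 8 libraries, run on 15174 IDs, the size rule gave 74 false calls in gill, so part of the IDs past it can come from spread that a counting interval does not hold.

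The set of liver-restricted IDs used to trace liver reads in the gut libraries was redefined after its first result was seen, because it held IDs read in the gut of both rivers, and both versions are given. A comparison of gut-restricted IDs with liver was dropped because the choice of these IDs fixed its outcome; another test, also chosen after seeing the data, took its place. Calculations were done in R 4.3.3 and figures drawn with matplotlib 3.10.9.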

Results

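Expression was measured in gill, gut, kidney and liver of brown trout from the river Hayle, chronically exposed to metals, and from the control river Teign, with 1 library of pooled fish for each river and tissue. The Hayle libraries held 1508163 reads for gill, 1740891 for gut, 1813092 for kidney and 2137983 for liver. The Teign libraries held 1730027 reads for gill, 1854599 for gut, 1487186 for kidney and 2178331 for liver. Of the 96683 gene IDs, 22856 had no read in any library. Liver was led by few transcripts: the 10 most abundant IDs took 33.0% of the Hayle and 26.7% of the Teign liver reads, against 6.42% and 7.04% in gill, 7.88% and 8.37% in kidney, and 17.7% and 19.4% in gut.

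The tissues differed far more than the rivers. Across gene IDs, which are not independent replicates, the Pearson correlation of log2 CPM was 0.885 to 0.933 between the rivers for the same tissue, and 0.446 to 0.681 between tissues of the same river. Gill had 1561 IDs higher and 1129 lower than the mean of the other 3 tissues. Gut had 1766 higher and 640 lower, kidney 1425 higher and 583 lower, and liver 1688 higher and 1416 lower. Of the higher IDs, 1327 in gill, 1391 in gut, 1113 in kidney and 1483 in liver exceeded every other tissue in both rivers. These counts come from edgeR's quasi-likelihood test over 2 pools of separate fish per tissue. They depend on the scaling: with library totals in place of TMM, gill had 3287 higher and 762 lower, gut 1642 and 711, kidney 2892 and 374, and liver 961 and 7080. Without the Hayle gill library 1022 IDs were higher in gill, and without the Teign gill library 943; without the Hayle gut library 359 were lower in gut, and without the Hayle liver library 830 were lower in liver. The remaining library of that tissue is then assumed to vary like the other tissues.

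The comparison of rivers within each tissue asked which transcripts differ between metal-exposed and control fish. Kidney held the most IDs past the size rule, 208 higher and 421 lower in Hayle, which is 3.88% of the 16224 compared. Liver had 141 higher and 156 lower of 9405 (3.16%), gut 100 higher and 265 lower of 13190 (2.77%), and gill 115 higher and 143 lower of 16198 (1.59%). In gut and kidney the lower IDs outnumbered the higher, with 27.4% and 33.1% of the IDs past the rule higher in Hayle, against 44.6% in gill and 47.5% in liver. The split turned in liver with other scalings, to 56.8% higher with library totals and 58.2% with TPM ratios, and in gill to 63.8% higher among IDs with at least 100 reads. The median log2 ratio lay between -0.05 and 0.02 in the 4 tissues. The differences have no replicate check and describe these libraries, not the rivers; a difference between tissues in these counts was not tested.

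**Figure D1:**
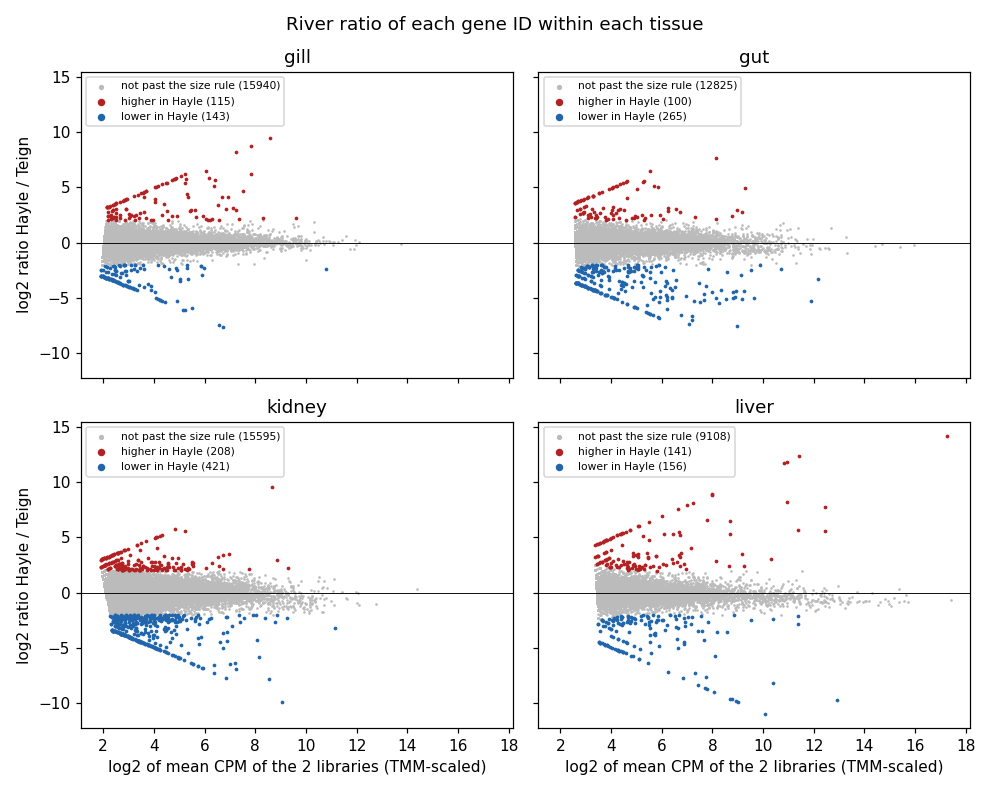
Log2 ratio of Hayle to Teign (vertical) against the log2 of mean TMM-scaled CPM (horizontal) for each gene ID with at least 20 reads over both libraries of a tissue, 1 point per ID, coloured where the ID passed the size rule. Kidney shows the most coloured points, 208 higher and 421 lower, and the straight outer lines of points are IDs with few or no reads in the other river.

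In liver, the IDs higher in Hayle held 17.1% of the Hayle liver reads, mostly through a single ID. This ID, chosen after its values were seen, had 305550 reads in Hayle liver, 14.3% of the library (95% Clopper-Pearson interval 14.2 to 14.3), and 14 reads in Teign liver. The ratio was 19619-fold, with a counting interval of 11693 to 35886. The log2 ratio with the prior count of 2, which the fold ratio does not have, was 14.17, and it was 12.96 from TPM with a pseudocount of 1. In the other 6 libraries it had 10 to 42 reads, a range that holds the 14 of Teign liver. Abundant liver IDs also left low counts in libraries of other tissues (described below). Whether the 14 reads are expression in Teign liver was not tested, so the ratio is uncertain beyond its counting interval. The Hayle library pools 5 fish, and how many of them carried the transcript cannot be told. Ratios whose whole counting interval lay beyond 100-fold were found for 8 higher and 10 lower IDs in liver, 1 higher and 4 lower in kidney, 3 higher and 2 lower in gill, and 1 of each in gut.

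Of the 582 gut-restricted IDs, 45 were lower in Hayle gut and 7 higher, where other IDs of matched abundance would give 5.19 and 2.54. Of the lower IDs, 31 were at least 8-fold lower and together held 2.34% of the Teign gut reads but 0.140% of the Hayle gut reads, with a median log2 ratio of -4.51. Of the 588 gill-restricted IDs, 15 were higher and 6 lower in Hayle gill, against 1.64 and 1.02 at matched abundance. Of the 276 kidney-restricted IDs, 4 were higher and 8 lower, against 1.83 and 3.98. Of the 763 liver-restricted IDs, 11 were higher and 23 lower, against 12.5 and 8.95. The median log2 ratio of the restricted IDs was -0.058 in gut, -0.056 in gill, 0.50 in kidney and -0.48 in liver. Whether the kidney and liver libraries of the rivers differ in tissue composition was not tested.

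**Figure D2:**
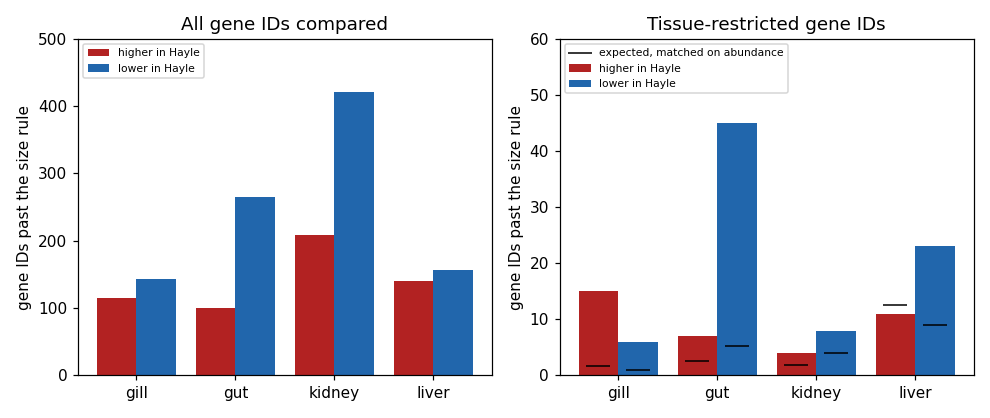
Number of gene IDs past the size rule (vertical) that were higher or lower in Hayle in each tissue (horizontal), for all IDs compared (left) and for tissue-restricted IDs (right), where black marks give the number expected at matched abundance. In gut, lower and higher IDs number 265 and 100 over all IDs and 45 and 7 among the gut-restricted, and in kidney 421 and 208 over all IDs.

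IDs past the size rule recurred between tissues more often than in independent lists. The correlation across IDs of the log2 ratio between pairs of tissues, which share no library, was 0.172 to 0.318 (mean 0.261; mean Spearman 0.187). Of the 1341 IDs past the size rule in at least 1 tissue, 94 were lower and 40 higher in Hayle in at least 2 tissues. Lower IDs coincided 192 times over the 6 pairs of tissues, where independent lists would give 5.65, and higher IDs 48 times, where they would give 2.16. Opposite directions also exceeded independent lists, with 27 IDs against 7.18. Passing the rule was thus not independent between tissues, and independent lists are too low a baseline for agreement in direction. In all 4 tissues 12 IDs were lower and 0 higher. Tissues of a river may share fish, so the recurrence can hold differences between these pools of fish.

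In the test for a river difference shared by the tissues, 118 of 20345 IDs passed, 101 lower and 17 higher in Hayle (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Not all of these were well covered throughout: 21 of the lower and 6 of the higher had at least 20 reads in each of the 4 tissue pairs, and 22 and 7 were mostly (at least 80%) in a single tissue. At an unadjusted p under 0.05 there were 1104 lower and 840 higher. Of the 101 lower IDs, 59 were lower in all 4 tissues, 57 had under 4 reads in total over the Hayle libraries, and 11 belonged to the 31 gut-restricted IDs described above. Of the 17 higher IDs, 11 were higher in all 4 tissues. Over all tested IDs, 17.6% had the same sign in all 4 tissues, against 12.5% by chance. The test selects for a common direction, so such agreement among its calls is partly built in. Among the higher IDs with at least 20 reads in each pair and higher in all 4 tissues, the one with the most Hayle reads, chosen after its values were seen, had 618 reads in Hayle gill against 89 in Teign gill. It had 1487 against 188 in gut, 747 against 202 in kidney and 1012 against 166 in liver (log2 fold change 2.47, SE 0.29, adjusted p = 0.00301 by edgeR). The number lower was 62 without the gut pair and 59 without the kidney pair, and the number higher was 10 without the liver pair. Limma-trend called 6 higher and 38 lower, and without the tissue block edgeR called 0, with 359 IDs at an unadjusted p under 0.05.

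The printed IDs lower in Hayle were absent from its libraries. The shared test therefore measured no spread between tissues for them, and their adjusted p rests on the spread of other IDs. The ID 3775976 had 0 reads in the 4 Hayle libraries against 113 in Teign gill, 191 in gut, 332 in kidney and 392 in liver. With a floor of 3 counts in place of 0, it was 32.3-fold lower in gill, 65.4-fold in gut, 149-fold in kidney and 145-fold in liver (edgeR adjusted p = 0.000135). The exact counting interval of its Hayle to Teign ratio reached up to 0.0387, 0.019, 0.00827 and 0.0085 in the same order. The ID ENSGACG00000020925 had 0 reads in the Hayle libraries against 40, 97, 125 and 201 in Teign gill, gut, kidney and liver. With the floor it was 11.4-fold, 33.2-fold, 56.3-fold and 74.5-fold lower (edgeR adjusted p = 0.000259). Its exact counting interval reached up to 0.113, 0.0377, 0.0222 and 0.0166. These ratios to the floor take the Teign counts as exact, so the intervals give the weaker bounds. Of the higher IDs, 188529830 had 952 reads in Hayle gut against 3 in Teign gut, a 309-fold ratio with a counting interval of 105 to 1500. It had 26 against 1 in liver, 8 against 0 in kidney and 2 against 0 in gill (log2 fold change 7.56, SE from the F statistic 0.56, edgeR adjusted p = 0.00015). With so few Teign reads this SE is likely too small. With the floor of 3 counts in place of 0 it was 1.97-fold higher in kidney, with a counting interval from 1.26 upward. In gill it was only 0.777-fold, with an interval from 0.219 upward, which shows no difference. Its Hayle CPM was 566 in gut, 26.6 in liver, 2.99 in kidney and 0.881 in gill. The shared fold change thus lay near the gut log2 ratio of 7.60, which has the prior count of 2 that the 309-fold ratio does not have. The ID gb|EG882237.1 had 91 reads in Hayle kidney against 2 in Teign kidney, 18 against 1 in gill, 16 against 3 in liver and 6 against 0 in gut (log2 fold change 3.95, SE from the F statistic 0.58, with the same limit, edgeR adjusted p = 0.0116). Its adjusted p rose to 0.0601 without the gill pair, 0.146 without the kidney pair and 0.0677 with limma-trend; that of 188529830 was 0.308 with limma-trend, and without the gut or the liver pair it was not tested. The log2 fold change of 188529830 was 3.50 with limma-trend and 5.96 with the DESeq2 Wald test, and that of gb|EG882237.1 was 2.69 and 4.01. Neither of these higher IDs passed the filter at a minimum count of 50 or with at least 20 reads in each tissue pair.

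**Figure D3:**
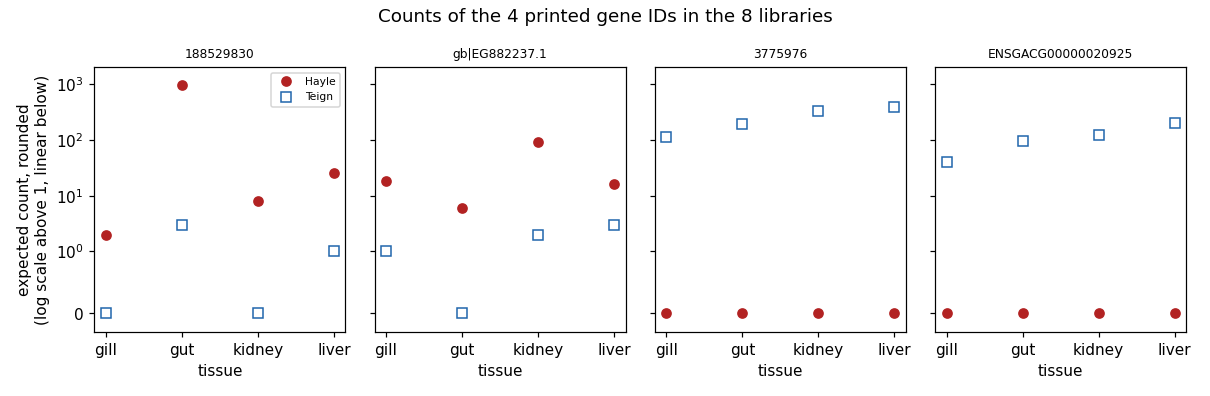
Rounded expected counts (vertical, log scale above 1) of the 4 printed gene IDs in each tissue (horizontal), 1 point per library. The IDs 3775976 and ENSGACG00000020925 lie at 0 in the 4 Hayle libraries and between 40 and 392 reads in the Teign libraries, and 188529830 reaches 952 reads in Hayle gut.

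Transcripts read in a single river were sought because the assembly joined both populations. With at least 10 reads in each of the 4 libraries of a river and under 1 in each library of the other, 8 IDs were read in Teign only and 0 in Hayle only. The 14 mixed sets of 4 libraries, with 1 library per tissue and both rivers among them, gave 0 each. At 5 reads or more, 18 IDs were read in Teign only and 1 in Hayle only, and mixed sets reached 2. At 50 reads or more the counts were 1 and 0.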

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

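The river ratio went in opposite directions in different tissues for 27 IDs, which passed the size rule as higher in Hayle in 1 tissue and as lower in another. Independent lists would give 7.18 such coincidences over the 6 pairs of tissues. The difference between tissues was not tested for these IDs, since each tissue has 1 library per river.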

How the results depend on the processing

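The filter on the reads of each tissue pair and the fits without the most abundant IDs were chosen after seeing the data. DESeq2 size factors, a prior count of 0.5 (size rule), the tissue fit without the river covariate and, for the river comparisons, leaving out the 10 most abundant IDs of each library left every count they were run on within 1.5 times its value. Alternatives for gene lists were not run, as no ID was paired with a name here. Scaling by library totals moved the median log2 ratio to 0.14 in gut, 0.13 in kidney and 0.13 in liver, and TPM ratios moved it to 0.12 in gill, 0.20 in gut, 0.22 in kidney and 0.36 in liver. At these depths 0 reads allows up to 1.12 CPM in Hayle kidney and up to 3.42 CPM in Teign liver.

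Under the size rule, counts higher and lower in Hayle without a filter, where more IDs are compared, were 223 and 250 in gill, 176 and 425 in gut and 225 and 285 in liver, and 718 were lower in kidney. With at least 100 reads, where fewer are compared, they were 44 and 25 in gill, 26 and 82 in gut, 46 and 85 in kidney and 42 and 52 in liver. The looser threshold (log2 ratio 1, interval excluding equality) gave 536 and 677, 622 and 895, 1473 and 1801, and 633 and 726 in the same order of tissues. The stricter (log2 ratio 3, interval beyond 4-fold) gave 63 and 87, 47 and 156, 52 and 218, and 70 and 78. With TPM ratios 92 IDs were lower in liver, and the cause was not tested.

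Shared calls higher and lower in Hayle were 236 and 496 without a filter, 2 and 25 at a minimum count of 50, where fewer IDs are tested, and 7 and 26 with at least 20 reads in each tissue pair. Limma-trend gave 6 and 38, the DESeq2 Wald test 46 higher, and library totals 26 higher; the cause was not tested. The fit without the tissue block, whose residual holds the tissue differences, gave 0 and 0. Leaving out each tissue pair gave 10 to 16 higher and 59 to 84 lower, where fewer libraries enter. Of the 101 lower and 17 higher calls, 62 and 11 were also called by the DESeq2 Wald test and 34 and 4 by limma-trend; leaving out a tissue pair kept 53 to 73 and 5 to 9.

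For tissue differences, library totals gave 3287 higher in gill, 2892 higher and 374 lower in kidney, and 961 higher and 7080 lower in liver. This setting leaves out the TMM factors. In Hayle and Teign they were 1.59 and 1.62 for gill, 1.56 and 1.41 for kidney, and 0.469 and 0.411 for liver. Without them liver values fall and gill and kidney values rise. Without a filter, where more IDs are tested, 2453 were higher in gill, 2390 in kidney and 2599 in liver. At a minimum count of 50 the counts were 563 higher and 746 lower in gill, 816 and 379 in gut, 559 and 382 in kidney, and 881 and 817 in liver. Leaving out each library gave 943 to 1890 higher in gill, 359 to 706 lower in gut and 830 to 1511 lower in liver. The mean Pearson correlation between tissues was 0.372 with at least 100 reads. For IDs read in a single river, 5 reads gave 1 for Hayle and 18 for Teign, 50 reads 1 for Teign, and under 5 reads in the other river 18 for Teign.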

Other observations

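The tests of an outside source of RNA, of a lower share of gut tissue, of the proportion of gut parts, of liver RNA in the Teign gut library and of index misassignment were chosen only after the results were seen.

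The number of IDs past the shared river test was compared with other splits of the 8 libraries into 4 and 4, with tissue as block. The libraries are paired by tissue, and 8 splits part all 4 pairs, too few for a share under 0.05. Of these 8, 1, the real split itself with 118 calls, gave as many, and the highest other gave 10. The 24 other splits that could be fitted keep 2 pairs together, compare something else, and gave at most 17.

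More shared calls were lower than higher in Hayle, and 57 of them were nearly absent from the Hayle libraries. A single outside source of RNA in the Teign fish would keep these IDs in the same ratio in each Teign library. Of them, 68.4% departed at least 4-fold, with a counting interval beyond 2-fold, from the summed profile of the others in a Teign library. In 100 simulations with 1 profile at most 3.51% did. Each simulated ID had the common dispersion of the 8 libraries (0.0759). IDs with few reads may vary more, which was not simulated. Within that limit, the departures argue against a single outside source as the whole source of the excess of lower calls. A chi-square test used first, which covers counting error only, gave 94.7%. Contigs specific to a population may account for part of the excess: at 5 reads or more against under 5, 13 IDs were read in Hayle only and 36 in Teign only, a ratio of 0.361. The exact 95% interval, 0.176 to 0.697, spans the 0.333 set in advance as the level such contigs would reach. That the interval, and not the value alone, must lie above it was decided after seeing the value. A mixed set gave 11, so the 13 Hayle IDs lie near that background. At 10 reads or more against under 5, where no mixed set held an ID, 0 were read in Hayle only and 18 in Teign only. That value lies below the level, but the unequal number of fish per pool may make the directions unequal by itself. The question thus stays open, as do a river difference in expression and the unequal number of fish per pool, which were not tested.

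Of the 582 gut-restricted IDs, 31 were far lower in Hayle gut. A lower share of gut tissue in the Hayle library would lower all 582 alike, but their median log2 ratio was -0.058. A different proportion of gut parts (stomach and intestine) in the dissections may give such a block. This and a river difference cannot be told apart, because each river has 1 gut library.

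Reads of 13 gut and 57 liver IDs, each with at least 5000 reads in its tissue and 99% of its reads there, also appeared at low rates in libraries of other tissues. Per 1000000 reads of the gut and of the liver IDs, Hayle gill held 118 and 117, Teign gill 116 and 153, Hayle kidney 154 and 352, and Teign kidney 136 and 314. Index misassignment between multiplexed libraries would give both sets similar rates, and the median ratio of the larger to the smaller was 1.80, but it was 2.29 and 2.31 in the kidney libraries, so misassignment may be part of it and does not account for all of the kidney reads if its rate was uniform. In Teign gut, 38 of these liver IDs were followed, with at least 5000 reads in Teign and 500 in Hayle liver. Of them, 78.9% were read at a higher rate than in Teign gill and kidney (81.0% of the 42 in the first version of the set). Liver RNA in the gut library was taken to give at least 90%. This level was chosen after the results were seen, so falling short of it does not decide the question. Rates of the 38 IDs were taken per 1000000 of their liver reads in the same river, not in both rivers as above. Pooled, they were 1456 in Teign gut, 254 in Teign gill and 661 in Teign kidney. In Hayle they were 350 in gut, 213 in gill and 967 in kidney. The Teign gut rate was 2.20 times the higher of Teign gill and kidney (95% bootstrap interval over IDs 1.13 to 5.24). Misassignment was taken to stay within 2 times. That the whole interval must lie on 1 side was decided after seeing the value. The median rate per ID was 1421 against 383 in the higher of Teign gill and kidney. The first version of the set had pooled rates of 19104.8 in Teign gut and 18590.5 in Hayle gut. From these values, liver RNA and index misassignment in Teign gut cannot be told apart. Whether the gut itself expressed some of the 38 IDs was not tested.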
